A study of Mus musculus with 5 samples.

How the data were processed

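Liver non-parenchymal cells of sham and pIVCL mice were profiled as 5 libraries with whole-transcriptome BD Rhapsody chemistry and DNBSEQ sequencing, from preparations of about 10000 viable cells at a viability above 70%. The deposited values are counts of molecules per gene and cell after correction of molecular identifiers by recursive substitution, per the file headers, made by the submitters with version 1.9.1 of the manufacturer's pipeline on GRCm39. The aligner and gene annotation are not given in the sources used here. Groups, replicate numbers and batches came from the sample labels. Gene lists, cell markers, tests and most alternatives were fixed before the data were examined, and alternatives added afterwards are named as such.

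The libraries (sham 1, sham 2, pIVCL 1, pIVCL 2, pIVCL 3) held 4735, 4056, 2680, 5000 and 3344 cells and 30523228, 25035721, 13532840, 24400965 and 12448260 molecules, with medians of 5416, 5125, 4226.5, 3878.5 and 2439.5 molecules per cell. Depth therefore was lower in pIVCL than in sham. Cells with under 500 molecules (0 in every library), under 200 genes (109, 117, 29, 617 and 261) or over 25% mitochondrial molecules (6.17, 5.52, 2.09, 29.9 and 11.0%) were left out, leaving 4441, 3831, 2601, 3484 and 2831. The hepatocyte list made up 0.239, 0.178, 0.260, 0.307 and 0.930% of the molecules of these cells and hemoglobin genes 0.0199, 0.0276, 0.0559, 0.143 and 0.269%. Scrublet scores in scanpy gave an automatic threshold that marked 40 cells (0.233%), so the 3% of cells with the highest score per library (516 in all) were removed, and the automatic threshold was not used. No ambient-RNA correction was made.

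Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes chosen by library gave 30 principal components, and Leiden clustering at resolution 1 on a graph of 20 neighbours gave 38 clusters without batch integration. A marker counted when detected in at least 25% of cells at 2-fold or more over cells of other classes. A cluster took a class when at least 3 and at least 50% of that class's markers counted. It stayed unnamed if markers of a second class were detected too, if its leading genes marked another class, or if it was shallow without leading markers. A Kupffer cluster also needed Clec4f in at least 50% of cells, a threshold set after the clusters were seen, which kept cluster 15 out of that class. Left out of the gene tests as unnamed were 12 clusters (1771 cells), 10 of them (1438 cells, 8.67 ± 2.54% of sham and 8.23 ± 4.93% of pIVCL cells) for second-class markers. Classes with under 20 cells in any library were not tested for genes.

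Molecule counts of each class were summed per library and compared by edgeR quasi-likelihood tests with robust dispersion, TMM scaling and filterByExpr, adjusted by Benjamini-Hochberg within a class at 0.05. CPM denotes TMM-scaled counts per 1e+06 molecules, and estimates are given ± SE, group means ± SD. Of 19736 genes with a molecule in any library 15468 had one in every library. Camera with a preset correlation of 0.01 tested lists with at least 5 genes and was repeated with an estimated correlation. The difference between the endothelial and Kupffer effects was an interaction in 1 model with library as a block within class. Shares were tested by two-sided exact permutation.

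Genes were named by a rule written in advance. In each class, among genes that passed with no overlap between the libraries of the groups and a mean log2 CPM of at least 5, and leaving out the lists of other cell types and RNA quality, antigen-receptor segments, histone and predicted genes, the 8 largest rises and 8 largest falls were taken (4 and 4 in classes other than endothelial, Kupffer and stellate), with the 4 members of lowest p of each list that passed and a set of genes picked beforehand. Genes named outside that rule were chosen after their values were seen, which holds for the further capillarization, pericentral and periportal genes.

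Alternatives were DESeq2 size factors, no expression filter, batch as a term, batch 2021.3 alone, replicate number as a block, leaving out each library, doublets kept, at least 1000 molecules with at most 10% mitochondrial, resolution 2, removal of hepatocyte, erythroid and neutrophil lists before scaling, DESeq2 Wald tests, and edgeR on cell counts. Added after the data were seen were stellate cluster 8 alone, endothelial cells without clusters 13, 17 and 23, Kupffer cells with cluster 11, and shares counting the mixed clusters.

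The gene test was tested on simulated data with 200 changed genes per class. At folds of 1.5, 2 and 4 it recovered 5.97, 64.2 and 87.9% among 11296 endothelial genes (13 unchanged genes among 118 calls), 11.9, 34.3 and 83.3% among 9809 Kupffer genes (13 of 99), 0, 4.48 and 60.6% among 8639 stellate and fibroblast genes (3 of 46), 1.49, 37.3 and 83.3% among 6025 T-cell genes (12 of 93), 0, 13.4 and 65.2% among 2892 NK and ILC1 genes (6 of 58) and 4.48, 16.4 and 77.3% among 6307 dendritic-cell genes (6 of 71). A gene that did not pass may therefore have changed, above all under 2-fold. Simulated lists were called 2 of 2 times with 1 other call among 32, and the interaction recovered 159 of 200 genes at fold 4, with 13 others, among 9419. Simulated genes were drawn independently of each other, so the list result cannot show how the list test behaves with correlated genes.

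Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.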

Results

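Single-cell RNA counts were analysed from liver non-parenchymal cells of wild-type male mice, operated on at 9 weeks of age and sampled 2 weeks after surgery that either narrowed the inferior vena cava by ligation (pIVCL) or was a sham. The ligation raises hepatic venous pressure and serves as a mouse model of congestive hepatopathy. Hepatocytes, dead cells and erythrocytes had been reduced by low-speed and Percoll centrifugation before capture on the BD Rhapsody system. There were 5 libraries, 2 from sham and 3 from pIVCL. Both sham libraries and pIVCL 1 belonged to batch 2021.3, whereas pIVCL 2 and pIVCL 3 belonged to batch 2021.7. Group and batch therefore overlap, and only pIVCL 1 can be set against sham within 1 batch. Of 19815 cells, 17188 passed the filters and 16672 were retained after doublet removal (4308 and 3716 in sham, 2523, 3379 and 2746 in pIVCL). The sources used here do not say whether each library came from a separate animal, so p-values measure the spread between these samples, which may be technical. An exact permutation test over the 10 splits of these libraries cannot give a two-sided p below 0.1.

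Stellate cells and fibroblasts made up a larger share of retained cells in every pIVCL library than in either sham library, at 11.8, 9.77 and 4.41% against 2.07 and 1.83%. The mean was 8.65 ± 3.81% (SD) in pIVCL and 1.95 ± 0.167% in sham, 4.44-fold higher. Within this class stellate cells (cluster 8) were 7.85 ± 3.68% of pIVCL and 1.14 ± 0.621% of sham cells. Fibroblasts (cluster 27) were not higher, at 0.794 ± 0.328% and 0.809 ± 0.455%. Endothelial cells, the most abundant class, held 59.5, 48.2 and 25.5% of pIVCL cells and 61.9 and 63.2% of sham cells. Kupffer cells held 8.32, 8.94 and 13.2% against 18.3 and 12.7%. B cells were at 2.22, 2.49 and 17.8% against 0.395 and 0.431%, the highest share lying in pIVCL 3. Conventional dendritic cells (2.68 ± 0.745% against 1.53 ± 0.0368%), monocytes (1.41% against 0.590%) and NK cells and ILC1 (1.85% against 0.780%) were also higher in each pIVCL library, while T cells were at 4.11% in pIVCL and 4.19% in sham. None of these shares passed a test. By exact two-sided permutation p was 0.2 for stellate cells and fibroblasts, endothelial cells, conventional dendritic cells, monocytes and NK cells and ILC1, 0.3 for Kupffer cells, 0.5 for B cells and 0.9 for T cells. The lowest adjusted p of this permutation test was 0.4 over the 12 classes. In edgeR quasi-likelihood fits to the cell counts with Benjamini-Hochberg adjustment, stellate cells and fibroblasts had a log2 fold change of 2.15 (adjusted p = 0.0823) and B cells 4.17 (adjusted p = 0.0823).

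Within batch 2021.3, pIVCL 1 minus sham was 9.82 percentage points for stellate cells and fibroblasts, -3.11 for endothelial cells, -7.15 for Kupffer cells, 1.81 for B cells and 0.447 for conventional dendritic cells. Without pIVCL 3 the difference moved from -18.2 to -8.73 points for endothelial cells and from 7.08 to 1.94 for B cells. It moved from 0.817 to 0.428 for monocytes, 1.07 to 0.594 for NK cells and ILC1 and 0.540 to 0.347 for neutrophils. The dendritic-cell difference of 1.14 became 0.749 without pIVCL 2, and that of B cells 4.12 with stricter filters. The Kupffer difference of -5.31 became -2.51 without sham 1, -8.11 without sham 2 and -7.97 with finer clusters. Hepatocytes were at 0.621 to 15.2% in pIVCL and 0.108 to 1.02% in sham, a difference of 5.05 points (0.262 without pIVCL 3). Neutrophils were 0 of 3716 cells in sham 2 (upper exact 95% limit 0.0992%), 0.116% in sham 1 and 0.598% on average in pIVCL (exact permutation p = 0.2). Those of sham 1 held 1.37% neutrophil-list (pIVCL at least 16.2%) and 3.61% endothelial-list molecules, so their class is doubtful. A gain in 1 share lowers the others, and shares depend on capture as well as tissue content.

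**Figure D1:**
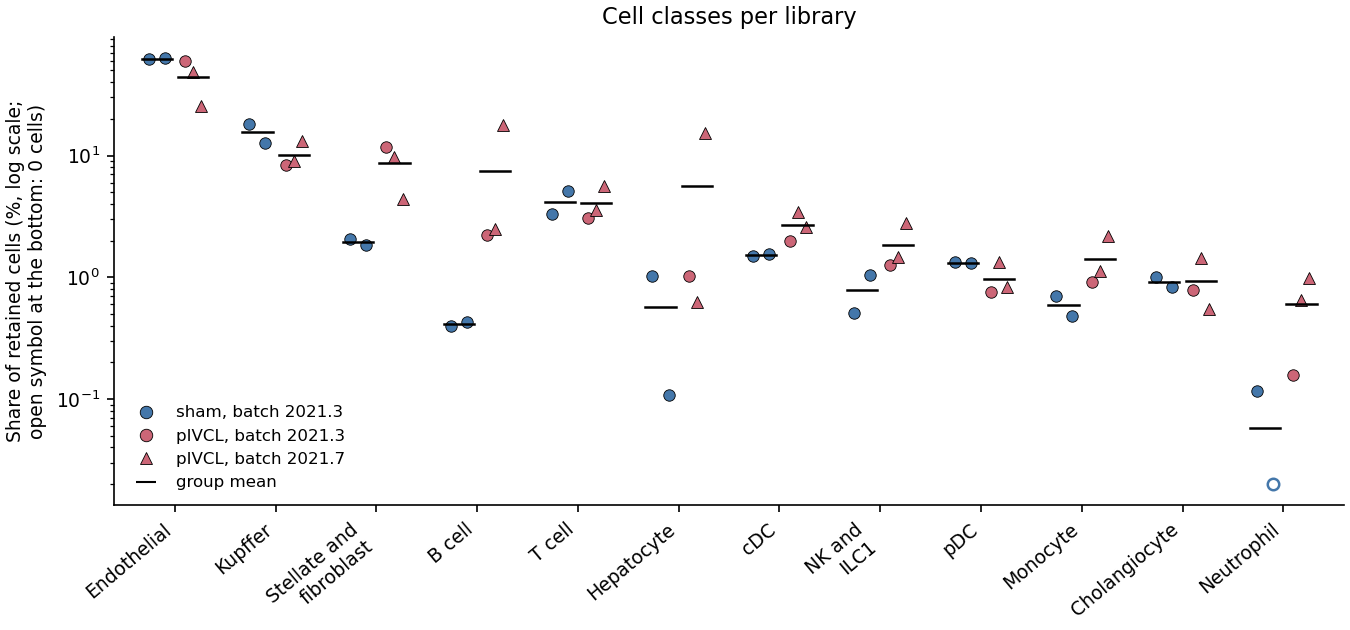
Share of retained cells per class and library. An open symbol marks a class with 0 cells in that library.

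In endothelial cells of pIVCL livers Esm1 (endocan, a marker of angiogenic tip cells) rose 10.6-fold, Angpt2 (a ligand of the receptor Tie2) 8.71-fold and Ccn2 (a matricellular target of YAP and TGF-beta) 17.2-fold. Pdgfb, whose product recruits stellate cells and pericytes, rose from 26.7 ± 2.01 to 165 ± 34.5 CPM, as did Plau (urokinase) and Kcnj8 (the pore of an ATP-sensitive potassium channel). Among the falls were those of Tiam1 (an exchange factor for Rac), Slco2a1 and Hpgd, which import and degrade prostaglandins, Gatm (creatine synthesis) and Ednrb (an endothelin receptor). Thrombomodulin (Thbd) fell from 173 ± 14.2 to 53.4 ± 6.65 CPM and the endothelial nitric oxide synthase gene Nos3 from 144 ± 17.6 to 83.9 ± 4.93. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, log2 fold changes (± SE) were 4.10 ± 0.45 for Ccn2 (adjusted p = 0.00716), 3.73 ± 0.33 for Kcnj8 (adjusted p = 0.00268) and 3.41 ± 0.18 for Esm1 (adjusted p = 0.000114). They were 3.12 ± 0.16 for Angpt2 (adjusted p = 0.000114), 2.62 ± 0.19 for Pdgfb (adjusted p = 0.000905) and 2.53 ± 0.24 for Plau (adjusted p = 0.00237). In the same fits Tiam1 was at -3.82 ± 0.28 (adjusted p = 0.00114), Slco2a1 at -2.61 ± 0.31 (adjusted p = 0.00851), and Hpgd at -2.39 ± 0.31 (adjusted p = 0.0106). Gatm was at -2.04 ± 0.35 (adjusted p = 0.0257), Ednrb at -1.98 ± 0.29 (adjusted p = 0.0168), Thbd at -1.69 ± 0.14 (adjusted p = 0.00114) and Nos3 at -0.78 ± 0.13 (adjusted p = 0.0164). Depp1, a FOXO target (4.05), and Susd4, a complement regulator (3.21), completed the 8 largest rises among genes of mean log2 CPM of at least 5 that the naming rule admits, and Slc26a10 (-2.84), Flrt1 (-2.02) and Sntb1 (-1.96) the 8 largest falls.

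In total 610 of 11296 endothelial genes passed, 304 higher and 306 lower in pIVCL, from 2664 before adjustment. For all 610 no pIVCL library overlapped a sham library, against 43.7% of all tested genes and a chance share of 20%. Passing a test on these same libraries all but requires such separation, so it is no separate support. Leaving out sham 1, sham 2, pIVCL 1, pIVCL 2 or pIVCL 3 gave 62, 82, 2566, 187 and 209 genes. Within batch 2021.3, where the lone pIVCL sample is assumed to vary like the others, 838 genes passed, 470 of them shared. A batch term rests the group effect on pIVCL 1, and with it 335 passed, 262 of them shared. Ccn2, Ednrb, Stab2, Mrc1, Tek, Edn1, Selp, Icam1, Lama5, Ifit3, Usp18, Oasl2, Slc2a1, Mup20 and Apoa1 no longer passed with the batch term, at log2 fold changes of the same sign. Most endothelial cells of sham lay in clusters 2 and 3 and most of those of pIVCL in clusters 1 and 4, which express the same class markers. Shares of endothelial cells in sham and pIVCL were 1.16 and 49.7% for cluster 1, 35.2 and 2.30% for cluster 2, 32.0 and 1.53% for cluster 3 and 12.2 and 23.3% for cluster 4. They were 5.92 and 2.78% for cluster 13 and 1.24 and 4.83% for cluster 17 (exact permutation p = 0.1 for each of these 6, the smallest possible, adjusted p = 0.133). Of the 10 leading genes of each, in the order given, 10, 7, 6, 3, 6 and 4 passed between the groups. These shifts therefore restate the gene changes in part and are no separate support. Cluster 6 held 11 ± 0.677% of endothelial cells in sham and 13.5 ± 9.55% in pIVCL (exact permutation p = 1), with a difference of -2.95 points without pIVCL 1 and 5.97 without pIVCL 3. The cycling cluster 23 held 1.25 ± 0.142% and 2.13 ± 1.08% (exact permutation p = 0.5). Erythroid-list transcripts made up 0.00804% of endothelial molecules in sham and 0.0629% in pIVCL, the hepatocyte list 0.0456% and 0.0991%, and mitochondrial transcripts 8.28% and 7.37%.

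**Figure D2:**
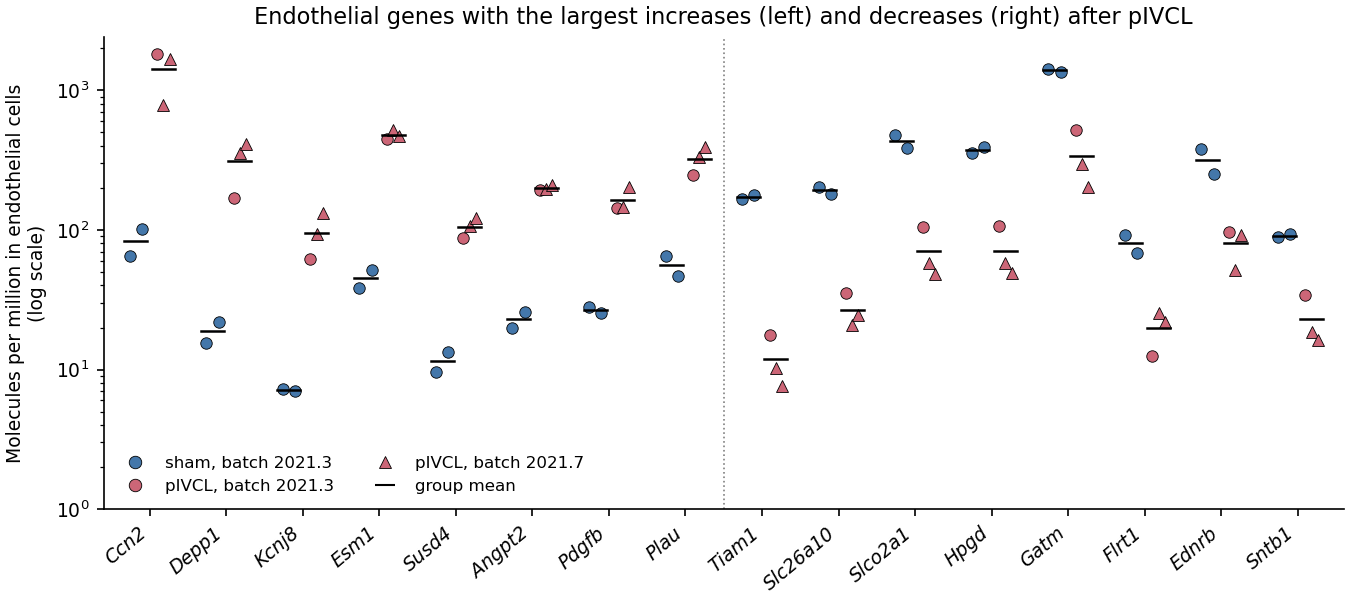
Expression in endothelial cells, in CPM, of the 8 genes with the largest rises and the 8 with the largest falls among those the naming rule admits, 1 point per library.

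Sinusoidal identity genes were lower as a list by camera with the preset correlation (adjusted p = 0.00021) and did not pass with an estimated one (adjusted p = 0.617). Of 24 identity genes measured, 5 fell (the scavenger receptors Stab2 and Mrc1, the angiopoietin receptor Tek, Plxnc1 and Tspan7), 1 rose (the hyaluronan receptor Lyve1) and 18 did not pass, and adjusted over the list alone 11 fell and 3 rose. Stab2 fell from 1695 ± 79.2 to 1087 ± 143 CPM, Lyve1 rose from 675 ± 21.9 to 3562 ± 1205, and Clec4g, at 3256 ± 212 and 2950.2 ± 554, did not pass. Among flow-responsive genes the calls were mixed, with Nos3, Thbd and the connexin gene Gja5 falling, Edn1 (endothelin) rising and 11 of 15 not passing, the counts being the same adjusted over the list alone. Log2 fold changes by edgeR quasi-likelihood with Benjamini-Hochberg adjustment were -0.64 ± 0.15 for Stab2 (adjusted p = 0.0474), 2.40 ± 0.31 for Lyve1 (adjusted p = 0.00845), 1.75 for Edn1 (adjusted p = 0.0466), -0.14 for Clec4g (adjusted p = 0.679) and -0.23 for the flow-induced factor Klf2 (adjusted p = 0.742). By camera the identity list had a median log2 fold change of -0.37 (adjusted p = 0.00021, adjusted p = 0.617 with an estimated correlation, lowest alternative 4.31e-06). The flow list was at -0.41 (adjusted p = 0.0132, adjusted p = 0.617 with an estimated correlation, lowest alternative 0.000951). The flow-list call ended without pIVCL 1 (adjusted p = 0.147), with a replicate block (adjusted p = 0.0666) and without the large-vessel and cycling clusters 13, 17 and 23 (adjusted p = 0.352).

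Targets of YAP and TEAD and angiocrine factors were higher as lists by camera with the preset correlation and did not pass with an estimated one (adjusted p = 0.363 for each). Of 16 YAP-TEAD targets 4 rose, among them Ccn2, Ajuba (2.07) and Crim1 (0.81), 0 fell and 6 rose adjusted over the list alone. Among 17 angiocrine factors 5 rose, including Angpt2, Pdgfb and Igf1 (1.36), and 2 fell, Hgf (hepatocyte growth factor, -1.23) and the pericentral ligand Wnt2 (-1.21), with 8 up and 4 down adjusted over the list alone. By camera the YAP-TEAD list had a median log2 fold change of 0.47 (adjusted p = 9.62e-06, adjusted p = 0.363 with an estimated correlation, lowest alternative 3.48e-09). The angiocrine list was at 0.67 (adjusted p = 0.0001, adjusted p = 0.363 with an estimated correlation, lowest alternative 7.13e-08). Hypoxia genes (17, of which Adm at 1.75 and Slc2a1 at 2.16 rose and 7 rose adjusted over the list alone) had a median of 0.38 (adjusted p = 0.000878, adjusted p = 0.363 with an estimated correlation, lowest alternative 0.000339). TGF-beta targets (11, of which 1, Ccn2, rose under either adjustment) had a median of 0.44 (adjusted p = 0.0132, adjusted p = 0.363 with an estimated correlation, lowest alternative 0.000568), a call that ended with batch as a term (adjusted p = 0.0915).

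Type I interferon and adhesion genes were higher as lists in endothelial cells at the preset correlation only (adjusted p = 0.617 and 0.363 with an estimated correlation). Of 19 type I interferon genes 3 rose (Ifit3 at 0.78, Usp18 at 0.87 and Oasl2 at 0.81) and, adjusted over the list alone, 10 rose and 1 fell. Of 18 adhesion and chemokine genes 3 rose under either adjustment, namely P-selectin (Selp, 1.91), Cxcl9 (1.57) and Icam1 (0.64), while Vcam1 (0.78, adjusted p = 0.135 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) did not pass. Of 17 basement membrane genes 3 passed, with Lamc1 (1.13) and Fbln5 (1.43) rising and the laminin gene Lama5 (-0.88) falling, and with 5 up and 1 down adjusted over the list alone. By camera the interferon list had a median of 0.78 (adjusted p = 6.45e-05, adjusted p = 0.617 with an estimated correlation, lowest alternative 2.17e-08). For the adhesion list it was 0.54 (adjusted p = 0.0132, adjusted p = 0.363 with an estimated correlation, lowest alternative 0.00111). For the basement membrane list it was 0.33 (adjusted p = 0.0343, adjusted p = 0.617 with an estimated correlation, lowest alternative 0.000646). The adhesion call ended without pIVCL 1 (adjusted p = 0.0512). The basement membrane call ended without sham 2 (adjusted p = 0.152), without pIVCL 3 (adjusted p = 0.0753), with batch as a term (adjusted p = 0.0802) and with a replicate block (adjusted p = 0.0769).

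Lists of hepatocyte and Kupffer-cell transcripts were higher in endothelial cells at the preset correlation only (adjusted p = 0.617 for each with an estimated correlation). Of 25 hepatocyte genes 5 rose, among them Ahsg (1.24), Mup20 (1.63), Apoa1 (1.31) and Serpina3k (1.43), 0 fell and 11 rose adjusted over the list alone. Of 9 Kupffer-cell genes 1 rose, the lysozyme gene Lyz2 (0.94), and 2 rose adjusted over the list alone. Of 13 mitochondrial genes mt-Nd4l (-0.92) fell, with 2 down adjusted over the list alone. By camera the medians in that order were 0.84 (adjusted p = 5.42e-10, adjusted p = 0.617 with an estimated correlation, lowest alternative 1.81e-30) and 0.89 (adjusted p = 0.00202, adjusted p = 0.617 with an estimated correlation, lowest alternative 1.16e-06) for the first 2. The mitochondrial list was at -0.31 (adjusted p = 0.021, adjusted p = 0.617 with an estimated correlation, lowest alternative 0.00109). The Kupffer-gene call ended with batch as a term (adjusted p = 0.387) and within batch 2021.3 (adjusted p = 0.373). The mitochondrial call ended without pIVCL 3 (adjusted p = 0.0753), with a replicate block (adjusted p = 0.0666) and with stricter filters (adjusted p = 0.0501).

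Genes of sinusoidal capillarization and zonation changed singly without a list passing. Plvap, which forms the diaphragms of capillary endothelium, rose from 269 ± 11.2 to 718 ± 232 CPM (log2 fold change 1.42, adjusted p = 0.0254 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment), whereas Cd34 (-0.85, adjusted p = 0.0793) and Vwf (-0.03, adjusted p = 0.960) did not pass. Of 17 capillarization genes Plvap, Esm1 and Edn1 rose and 6 fell, among them Ly6c1 (-2.61), Ly6a (-1.26) and the tight-junction gene Cldn5 (-0.67), and adjusted over the list alone 4 rose and 9 fell. The list had a median of -0.57, a mean of 0.11 and a camera test on the lower side (adjusted p = 0.203). Of 14 pericentral genes Wnt2, Kit (-1.46), Thbd and Ramp3 (-2.08) fell and Fabp4 (1.31) rose (median -0.28, camera adjusted p = 0.0696), with Rspo3 at 0.95 (adjusted p = 0.114 by the gene model) not passing. Of 11 periportal genes Dll4 (0.93) and Galnt15 (1.5) rose and Adgrg6 (-0.76) fell (median 0.23, camera adjusted p = 0.371).

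**Figure D3:**
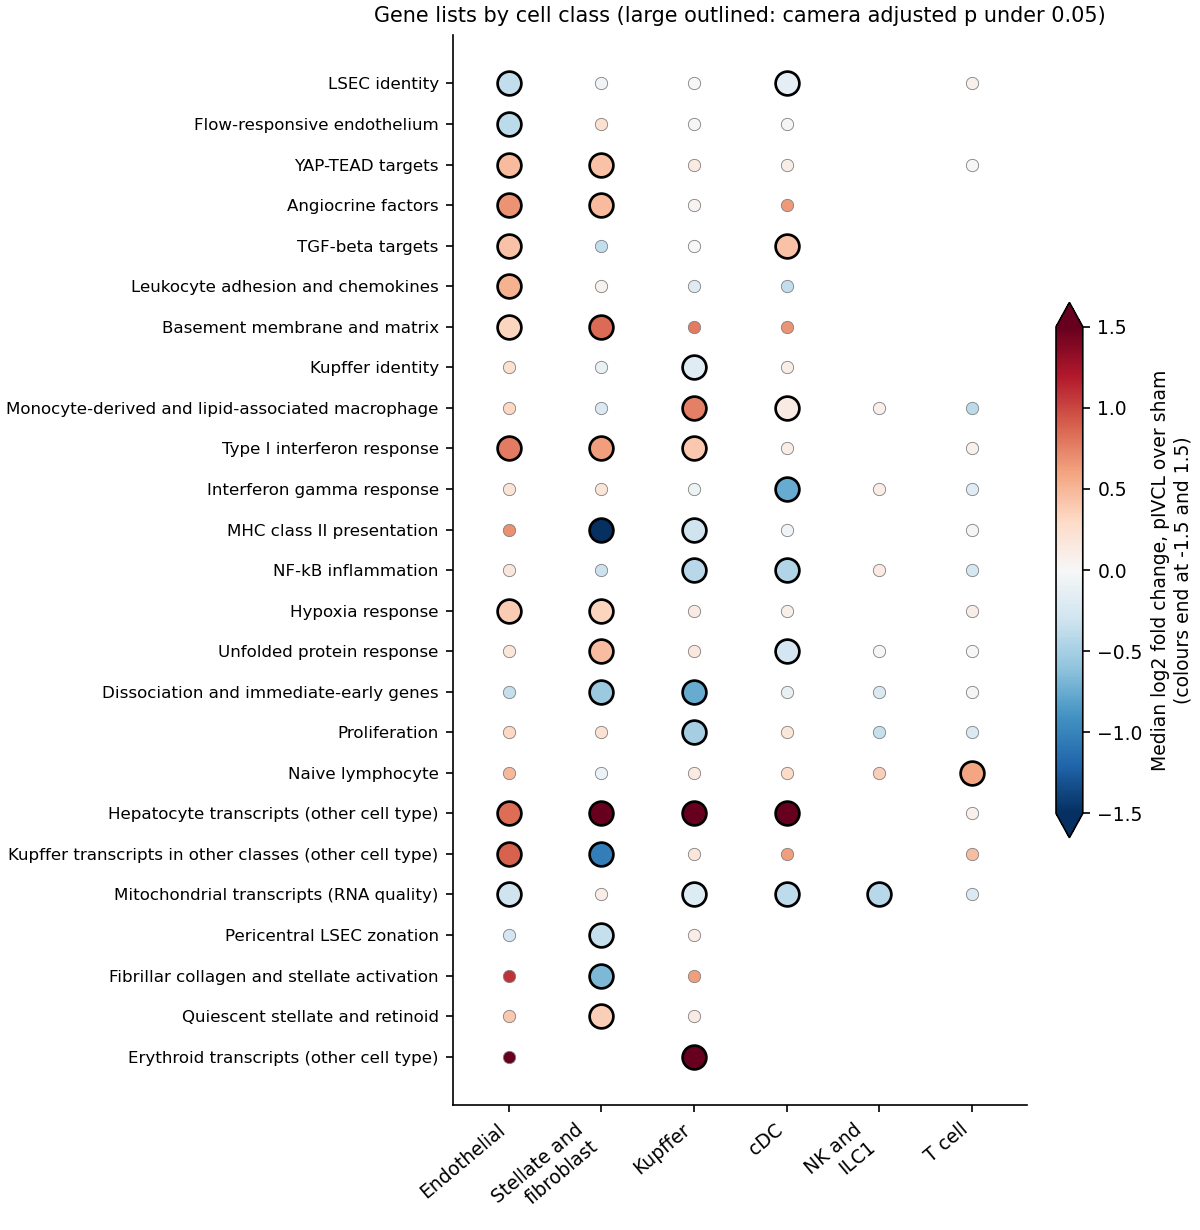
Median log2 fold change, pIVCL over sham, of each gene list that passed camera in at least 1 class. Large outlined points passed with the preset correlation and none of them passed with an estimated correlation.

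Kupffer cells of pIVCL livers expressed more of the adhesion molecule Vcam1, from 449 ± 32.8 to 1082 ± 117 CPM, and of the platelet chemokine gene Pf4, from 55.3 ± 4.52 to 119 ± 9.01. The nuclear receptor gene Nr4a1, an immediate-early gene in macrophages, fell from 125 ± 8.32 to 52.0 ± 12.5 CPM. Clec4f, the marker that set the class apart, was at 5178 ± 108 and 5203 ± 81.4 CPM, and the resident-macrophage receptor Timd4 at 1019 ± 21.0 and 598 ± 94.8 did not pass. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, log2 fold changes were 1.27 ± 0.14 for Vcam1 (adjusted p = 0.0293), 1.11 ± 0.15 for Pf4 (adjusted p = 0.0316) and -1.28 ± 0.18 for Nr4a1 (adjusted p = 0.0468). They were 2.61 ± 0.33 for the hepatocyte fibrinogen gene Fga (adjusted p = 0.0293), 0.01 for Clec4f (adjusted p = 0.987) and -0.77 for Timd4 (adjusted p = 0.109). In all 10 of 9809 genes passed, 5 in each direction, from 1372 before adjustment. Their libraries did not overlap between groups, as passing on these libraries all but requires, against 32.0% of all tested genes and a chance share of 20%. The other 6, named after their values were seen, were Clu (2.56), Cyp3a11 (2.03, a hepatocyte cytochrome), Tob1 (-1.67), Lsp1 (-1.85), the leukotriene synthase gene Ltc4s (-1.92) and Krt80 (-2.50).

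The Kupffer gene calls depended on which libraries were included. With edgeR, 0 genes passed without sham 1, without sham 2 and without pIVCL 2 (526, 508 and 1180 before adjustment), 1 passed without pIVCL 3 and 416 without pIVCL 1, and DESeq2 gave 120 on all libraries, 81 higher and 39 lower. A replicate block gave 10 higher and 2 lower. Vcam1, Pf4 and Nr4a1 no longer passed with batch as a term, while within batch 2021.3 Vcam1 (adjusted p = 0.00499) and Pf4 (adjusted p = 0.0275) passed in the edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment. Cluster 5 held 80.7 and 82.0% of Kupffer cells in sham and 54.3, 14.6 and 6.06% in pIVCL, and cluster 7 held 13.5 and 12.7% against 41.9, 80.8 and 92.3%. Erythroid transcripts made up 0.00284% of Kupffer molecules in sham and 0.0853% in pIVCL, and the hepatocyte list 0.338% and 0.382%.

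In Kupffer cells the lists of immediate-early, proliferation and identity genes were lower, and that of monocyte-derived and lipid-associated macrophages higher, by camera with the preset correlation, although Nr4a1 was their only member to pass. With an estimated correlation adjusted p was 0.919 for the first 3 and 0.580 for the last. Of 11 genes of the macrophage list 0 passed over all genes and 4 rose adjusted over the list alone, with Trem2 at 0.73 (adjusted p = 0.202), the monocyte chemokine receptor Ccr2 at 1.5 (adjusted p = 0.109) and Cd63 at 1.61 (adjusted p = 0.132) by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Of 23 identity genes, among them Timd4, Marco (0.18), Vsig4 (0.25) and Cd5l (0.19), 0 passed over all genes, and adjusted over the list alone 4 fell and 1 rose. The separate list of Kupffer-cell transcripts made up 4.60% of the molecules of this class in sham and 5.12% in pIVCL. Of 21 immediate-early genes Nr4a1 fell, and 2 fell adjusted over the list alone. Of 22 proliferation genes such as Mki67 (-0.97) 0 passed over all genes and 1 fell over the list alone. By camera the macrophage list had a median of 0.75 (adjusted p = 0.000598, adjusted p = 0.580 with an estimated correlation, lowest alternative 1.09e-05). For identity it was -0.18 (adjusted p = 0.0198, adjusted p = 0.919 with an estimated correlation, lowest alternative 0.000501). For immediate-early genes it was -0.75 (adjusted p = 2.53e-05, adjusted p = 0.919 with an estimated correlation, lowest alternative 1.56e-20). For proliferation it was -0.51 (adjusted p = 0.000131, adjusted p = 0.919 with an estimated correlation, lowest alternative 1.3e-09). Under a batch term and then within batch 2021.3, adjusted p was 0.359 and 0.0514 for immediate-early genes, 0.313 and 0.111 for proliferation and 0.313 and 0.334 for identity. The macrophage list did not pass with batch as a term (adjusted p = 0.067). The identity call also ended without sham 1 (adjusted p = 0.113), without pIVCL 2 (adjusted p = 0.144) and with finer clusters (adjusted p = 0.174). The proliferation call ended with a replicate block (adjusted p = 0.0513).

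The type I interferon list was higher, and the NF-kB and MHC class II lists lower, in Kupffer cells by camera with the preset correlation, with no member of any past the threshold. With an estimated correlation adjusted p was 0.919 for all 3, and the NF-kB list turned upward within batch 2021.3 and with a batch term. Of 19 interferon genes, including Isg15 (0.90) and Irf7 (0.73), 0 passed over all genes and 5 rose adjusted over the list alone. Of 21 NF-kB genes such as Il6 (-2.89) 0 passed over all genes and 1 fell over the list alone, and of 11 MHC class II genes 0 passed either way. By camera interferon genes had a median of 0.40 (adjusted p = 0.000149, adjusted p = 0.919 with an estimated correlation, lowest alternative 3.4e-08). For NF-kB it was -0.41 (adjusted p = 0.0384, adjusted p = 0.919 with an estimated correlation, lowest alternative 1.64e-09). For MHC class II it was -0.31 (adjusted p = 0.0468, adjusted p = 0.919 with an estimated correlation, lowest alternative 1.59e-07). The NF-kB list turned upward and did not pass with batch as a term (median 0.22, adjusted p = 0.313) and within batch 2021.3 (median 0.21, adjusted p = 0.111). It also ended without sham 1 (adjusted p = 0.113), pIVCL 2 (adjusted p = 0.135) or pIVCL 3 (adjusted p = 0.173). The interferon call ended with batch as a term (adjusted p = 0.313), within batch 2021.3 (adjusted p = 0.254) and without sham 1 (adjusted p = 0.113). The MHC class II call ended with batch as a term (adjusted p = 0.584), within batch 2021.3 (adjusted p = 0.576), without sham 2, where the test turned upward at a median of -0.21 (adjusted p = 0.876), and without pIVCL 2 (adjusted p = 0.214). It was also lost without pIVCL 3 (adjusted p = 0.0814), with a replicate block (adjusted p = 0.0915), with finer clusters (adjusted p = 0.0699) and with hepatocyte, erythroid and neutrophil lists removed (adjusted p = 0.0558).

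Hepatocyte and erythroid lists were higher and the mitochondrial list lower in Kupffer cells at the preset correlation only (adjusted p = 0.580, 0.919 and 0.919 with an estimated correlation). Of 25 hepatocyte genes Fga rose, and adjusted over the list alone 20 rose and 1 fell. Of 6 erythroid genes and of 13 mitochondrial genes 0 passed over all genes. By camera hepatocyte genes had a median of 1.61 (adjusted p = 8.94e-25, adjusted p = 0.580 with an estimated correlation, lowest alternative 5.35e-53). For erythroid genes it was 4.86 (adjusted p = 0.00205, adjusted p = 0.919 with an estimated correlation, lowest alternative 3.81e-44). For mitochondrial genes it was -0.20 (adjusted p = 0.0468, adjusted p = 0.919 with an estimated correlation, lowest alternative 0.000357). The erythroid call ended with batch as a term (adjusted p = 0.191) and within batch 2021.3 (adjusted p = 0.111). The mitochondrial call was lost without sham 1 (adjusted p = 0.113), pIVCL 1 (adjusted p = 0.0701) or pIVCL 3 (adjusted p = 0.206), with a replicate block (adjusted p = 0.167) and with hepatocyte, erythroid and neutrophil lists removed (adjusted p = 0.0558). Heme and iron handling genes did not pass as a list of 19 (median 0.07, adjusted p = 0.491 by camera). Hmox1, which degrades heme, was at 1158 ± 72.9 and 1531 ± 195 CPM (log2 fold change 0.40, adjusted p = 0.274 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and did not pass. Nor did the hemoglobin scavenger receptor Cd163 at -0.28 (adjusted p = 0.515) or the iron exporter gene Slc40a1 at -0.19 (adjusted p = 0.586).

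Stellate cells and fibroblasts gained transcripts of the growth-factor-binding gene Igfbp3, from 389 ± 194 to 4839 ± 377 CPM, of the vasodilator peptide gene Adm, from 78.6 ± 40.8 to 479 ± 24.0, and of the chemokine gene Cxcl14. The mesodermal gene Mest, Rtn1 and the LIM-domain gene Ajuba also rose. Cd34, a surface marker of fibroblasts and endothelium, fell from 189.9 ± 69.3 to 28.1 ± 9.91 CPM, together with the proteoglycan gene Vcan, Dpysl3, Smoc2 and Gatm. Fos, an immediate-early gene sensitive to cell dissociation, fell from 1802 ± 588 to 480.1 ± 68.6 CPM. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, log2 fold changes were 3.63 ± 0.35 for Igfbp3 (adjusted p = 0.00349), 3.17 ± 0.39 for Cxcl14 (adjusted p = 0.0131) and 2.61 ± 0.30 for Adm (adjusted p = 0.0074). They were 2.47 for Mest (adjusted p = 0.015), 2.19 for Rtn1 (adjusted p = 0.0207) and 2.15 for Ajuba (adjusted p = 0.0157). Among the falls they were -2.81 ± 0.32 for Cd34 (adjusted p = 0.00704), -2.51 for Vcan (adjusted p = 0.015), -2.19 for Dpysl3 (adjusted p = 0.0134), -1.93 for Smoc2 (adjusted p = 0.0272) and -1.91 ± 0.25 for Fos (adjusted p = 0.0107). Activation genes did not pass, with Col1a1 at -1.31 (adjusted p = 0.296, 9606 ± 3786 CPM in sham and 3879 ± 1938 in pIVCL), Acta2 at 1.21 (adjusted p = 0.273), Timp1 at -2.45 (adjusted p = 0.423) and the retinoid gene Lrat at 0.18 (adjusted p = 0.841). Of 8639 genes 70 passed, 44 higher and 26 lower, from 1223 before adjustment. All were without overlap between groups, as passing on these libraries all but requires (33.5% of all tested genes, chance share 20%). The split was 46 higher and 58 lower with batch as a term, 47 and 76 within batch 2021.3, 34 and 35 with a replicate block and 100 and 101 by DESeq2.

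This class joined stellate cells (cluster 8) to fibroblasts (cluster 27), in unequal mixtures. Fibroblasts were 23.6 and 61.8% of the class in sham and 9.76, 5.15 and 16.5% in pIVCL. In cluster 8 alone, an alternative chosen after the data were seen, 15 genes passed and all rose, 9 of them shared, with log2 fold changes of 3.04 for Igfbp3, 2.43 for Cxcl14, 2.82 for Adm and 1.69 for Rtn1. Several falls shrank or turned there, with Dpysl3 at -0.58, Smoc2 at -0.09, Pid1 at 0.85 against -2.02 in the whole class, and Col1a1 at 0.71. Without sham 2, the library with the most fibroblasts, 7 genes passed, without pIVCL 2 there were 10 and without pIVCL 1 there were 310. Within batch 2021.3 alone 123 passed, 44 of them shared. Lsp1, Smoc2, Lamc1 and Vipr1 no longer passed with batch as a term.

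Basement membrane genes and targets of YAP and TEAD were higher as lists in stellate cells and fibroblasts at the preset correlation only (adjusted p = 0.300 and 0.262 with an estimated correlation). Of 18 basement membrane genes the laminin gene Lamc1 (1.60) and the nidogen gene Nid2 (1.56) rose and 1, Vcan, fell, with 9 up and 2 down adjusted over the list alone. In cluster 8 alone these were at 1.39 and 1.70. Of 19 YAP-TEAD targets 2, Igfbp3 and Ajuba, rose, with 8 up and 3 down over the list alone, and Ccn2 at 0.95 (adjusted p = 0.129 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) did not pass. Angiocrine factors (14 genes, 0 past over all genes and 5 up over the list alone) and hypoxia genes (13, of which Adm rose under either adjustment) were tested as well. By camera basement membrane had a median of 0.85 (adjusted p = 3.11e-05, adjusted p = 0.300 with an estimated correlation, lowest alternative 5.32e-15). For YAP-TEAD it was 0.44 (adjusted p = 0.000452, adjusted p = 0.262 with an estimated correlation, lowest alternative 7.98e-11). For angiocrine factors it was 0.47 (adjusted p = 0.000958, adjusted p = 0.300 with an estimated correlation, lowest alternative 0.000124). For hypoxia it was 0.34 (adjusted p = 0.0128, adjusted p = 0.300 with an estimated correlation, lowest alternative 0.00181). The angiocrine call ended with batch as a term (adjusted p = 0.119), within batch 2021.3 (adjusted p = 0.29) and without pIVCL 2 (adjusted p = 0.0502). The hypoxia call was lost without sham 1 (adjusted p = 0.175), without pIVCL 1 (adjusted p = 0.0721) and with a replicate block (adjusted p = 0.0508).

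Fibrillar collagen and activation genes were lower as a list in the whole class and higher in stellate cells alone at the preset correlation, and did not pass in the whole class with an estimated one (adjusted p = 0.360). Of 24 genes 0 passed over all genes, and adjusted over the list alone 9 fell and 5 rose, with Col3a1 at -0.60 (adjusted p = 0.312) and Col6a3 at -1.40 (adjusted p = 0.0639) by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. By camera the median was -0.67 (adjusted p = 0.00261, adjusted p = 0.360 with an estimated correlation, alternatives from 0.000123 to 0.744). In cluster 8 alone it was 0.64 (adjusted p = 0.000123), where Col3a1 was at 1.19. That call also ended without sham 2 (adjusted p = 0.0552), with batch as a term (adjusted p = 0.224), within batch 2021.3 (adjusted p = 0.117) and with stricter filters (adjusted p = 0.744). Quiescent stellate genes (16, of which Vipr1 at 1.38 rose and, over the list alone, 7 rose and 1 fell) had a median of 0.37 (adjusted p = 0.000184, adjusted p = 0.395 with an estimated correlation, alternatives from 8.16e-08 to 0.677). It became -0.07 in cluster 8 alone (adjusted p = 0.677) and did not pass without sham 2 (adjusted p = 0.083). Genes of the pericentral endothelial list (9, of which 1, Dkk3, fell and 3 fell over the list alone) had a median of -0.35 (adjusted p = 0.0182, adjusted p = 0.300 with an estimated correlation, alternatives from 0.00212 to 0.374). That call was lost without sham 1, at a median of 0.23 (adjusted p = 0.0606), and without pIVCL 1 (adjusted p = 0.374).

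MHC class II and immediate-early lists were lower, and type I interferon and unfolded protein lists higher, in stellate cells and fibroblasts at the preset correlation only. With an estimated correlation adjusted p was 0.262, 0.459, 0.395 and 0.548 in that order. Of 5 MHC class II genes 2 fell, H2-Aa (-1.84) and the cathepsin gene Ctss (-1.99), and all 5 fell adjusted over the list alone, while Cd74 (-1.73, adjusted p = 0.0883 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) did not pass over all genes. Of 21 immediate-early genes Fos fell, and 2 fell over the list alone. Of 18 interferon genes 0 passed over all genes and 3 rose over the list alone, with Isg15 at 1.34. Of 13 unfolded protein genes 1 rose over the list alone, with the stress-induced secreted factor gene Manf at 1.37 and 0 past over all genes. By camera MHC class II had a median of -1.99 (adjusted p = 2.24e-13, adjusted p = 0.262 with an estimated correlation, alternatives from 1.78e-27 to 0.284). For immediate-early genes it was -0.56 (adjusted p = 7.42e-05, adjusted p = 0.459 with an estimated correlation, lowest alternative 2.56e-09). For interferon genes it was 0.63 (adjusted p = 7.52e-06, adjusted p = 0.395 with an estimated correlation, lowest alternative 2.57e-10). For unfolded protein genes it was 0.46 (adjusted p = 0.0182, adjusted p = 0.548 with an estimated correlation, lowest alternative 0.0025). In cluster 8 alone the MHC class II list (adjusted p = 0.284) and the immediate-early list (adjusted p = 0.0553) did not pass, nor did the latter without sham 2 (adjusted p = 0.14). Under a batch term and then within batch 2021.3, adjusted p was 0.0972 and 0.0791 for interferon genes and 0.406 and 0.313 for unfolded protein genes. The latter call also ended without sham 2 (adjusted p = 0.0606) and without pIVCL 2 (adjusted p = 0.0729).

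Hepatocyte transcripts were higher as a list in stellate cells and fibroblasts at the preset correlation only (adjusted p = 0.262 with an estimated correlation). Of 24 hepatocyte genes 9 rose, among them albumin (Alb), from 124 ± 41.8 to 758 ± 66.6 CPM, the fetuin gene Ahsg and the fibrinogen genes Fga and Fgb, 0 fell and 21 rose adjusted over the list alone. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, log2 fold changes were 2.61 ± 0.26 for Alb (adjusted p = 0.00349), 2.93 for Ahsg (adjusted p = 0.00743), 3.69 for Fga (adjusted p = 0.015) and 3.86 for Fgb (adjusted p = 0.0107). Within cluster 8 Alb was at 2.29 and Ahsg at 2.37. By camera the list had a median of 2.27 (adjusted p = 4.72e-40, adjusted p = 0.262 with an estimated correlation, lowest alternative 2.09e-48). It made up 0.0887% of the molecules of this class in sham and 0.333% in pIVCL, against 0.0879% and 0.0954% in T cells. Of 8 Kupffer-cell genes 0 passed over all genes and 2 fell over the list alone (median -1.04, adjusted p = 0.000159, adjusted p = 0.360 with an estimated correlation, lowest alternative 1.6e-08). In cluster 8 alone that list was higher by camera with the preset correlation (median 0.93, adjusted p = 0.00874), and an estimated one was not tried there.

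**Figure D4:**
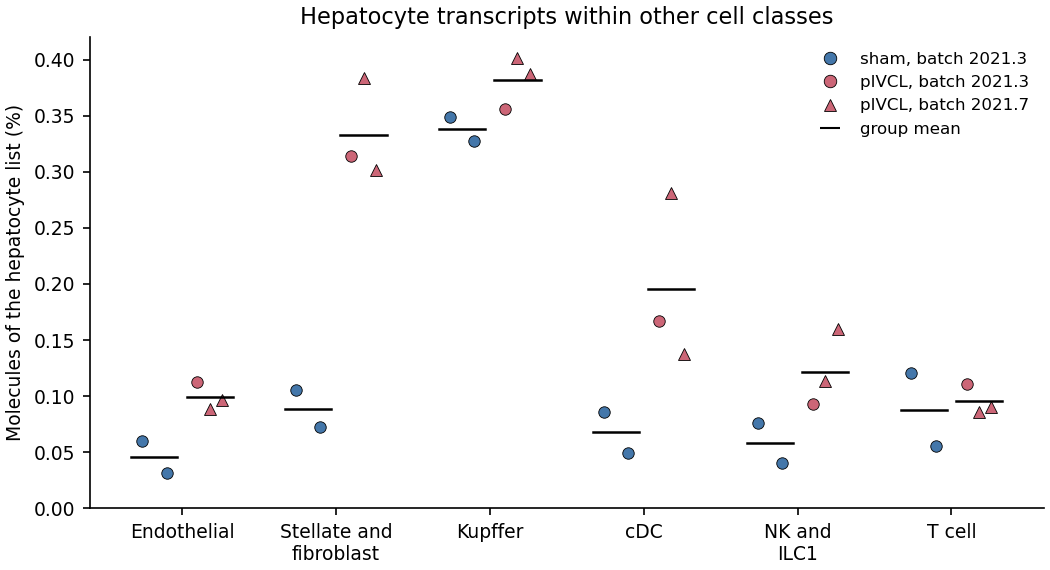
Molecules of the hepatocyte gene list as a percentage of all molecules of each class, 1 point per library.

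In T cells the list of naive-lymphocyte genes was higher at the preset correlation only (adjusted p = 0.920 with an estimated correlation), with 1 of its 10 genes past the threshold. That gene, Klf2, which drives the lymphoid-homing programme of naive T cells, rose from 219 ± 68.4 to 688 ± 97.6 CPM, Foxp4 from 22.2 ± 6.78 to 92.3 ± 4.67, and the actin crosslinker gene Actn1 also rose. The activation-linked surface gene Ly6a fell from 839.6 ± 142 to 405 ± 107 and Asb2 fell too. Of 10 naive-lymphocyte genes Klf2 rose, and 8 rose adjusted over the list alone. Bach2 was at 1.2 (adjusted p = 0.129) in the edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment. In that fit log2 fold changes were 1.67 ± 0.21 for Klf2 (adjusted p = 0.000432), 2.02 ± 0.36 for Foxp4 (adjusted p = 0.027), 1.26 for Actn1 (adjusted p = 0.027), -1.26 for Asb2 (adjusted p = 0.0351) and -1.07 for Ly6a (adjusted p = 0.0324). By camera the naive list had a median of 0.59 (adjusted p = 1.2e-11, adjusted p = 0.920 with an estimated correlation, lowest alternative 9.04e-15). Cytotoxic effectors (12 genes, median -0.08, adjusted p = 0.772) and activation and checkpoint genes (9, median 0.07, adjusted p = 0.772) did not pass.

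The 5 T-cell genes were all that passed of 6025 (585 before adjustment). Their libraries did not overlap between groups, as passing on them all but requires, against 24.8% of all tested genes and a chance share of 20%. With stricter filters 0 genes passed by edgeR (458 before adjustment), so Klf2 lost its call there too. Without sham 1, sham 2, pIVCL 1, pIVCL 2 or pIVCL 3 the count was 23, 13, 121, 2 and 1. In the batch-term fit only Klf2 (1.41) of the 5 passed, and within batch 2021.3 there were 7 genes, Klf2 being the 1 shared. Cluster 12 held 73.2 and 82.5% of T cells in sham and 59.0, 53.7 and 45.2% in pIVCL. Cluster 16, whose leading genes include the naive-list members Tcf7, Il7r and Lef1, held 26.8 and 17.5% against 41.0, 46.3 and 54.8%, so the list was measured in different mixtures of naive and other T cells.

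In NK cells and ILC1 1 gene passed. Mt-Nd4l, encoding a subunit of respiratory complex I, fell from 4771 ± 875 to 2343 ± 291 CPM (log2 fold change -1.03 ± 0.21, adjusted p = 0.0335 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment), the only 1 of 2892 genes to pass (199 before adjustment). The endothelial list made up 1.00% of the molecules of this class in sham 1, which stood apart, against 0.0582% in sham 2 and 0.0408, 0.0327 and 0.00931% in pIVCL. Libraries for mt-Nd4l did not overlap between groups, as passing on them all but requires, against 23.6% of all tested genes and a chance share of 20%. Of 12 mitochondrial genes 5 fell adjusted over the list alone (median -0.41, camera adjusted p = 2.58e-06, adjusted p = 0.427 with an estimated correlation, lowest alternative 1.53e-06). Mitochondrial transcripts were 9.81% of NK and ILC1 molecules in sham and 7.84% in pIVCL. That list did not pass with stricter filters (adjusted p = 0.104), and cytotoxic effectors (13 genes, median -0.11, adjusted p = 0.533) did not pass. With edgeR 0 genes passed without sham 1, pIVCL 2 or pIVCL 3 (152, 114 and 113 before adjustment), 77 passed without sham 2 and 3 without pIVCL 1, and DESeq2 gave 2 on all libraries. The call of mt-Nd4l also ended with batch as a term (adjusted p = 0.650), within batch 2021.3 (adjusted p = 0.168), with doublets kept (adjusted p = 0.295) and with stricter filters (adjusted p = 0.547).

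In conventional dendritic cells of pIVCL livers 5 genes rose and 3 fell. The monocyte and macrophage gene F13a1 rose from 12.3 ± 3.05 to 161 ± 25.7 CPM, and the monocyte gene Ly6c2 from 32.8 ± 29.3 to 389.9 ± 105. The interleukin 12 subunit gene Il12b, a leading gene of the small cluster 38 (8, 4, 2, 7 and 11 cells per library), fell from 225 ± 58.3 to 10.1 ± 8.82 CPM and was 0 in pIVCL 1, and the receptor gene P2ry10 and Serpinb6b fell too. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, log2 fold changes were 3.67 ± 0.38 for F13a1 (adjusted p = 1.64e-05) and 3.59 ± 0.47 for Ly6c2 (adjusted p = 0.0318). They were -4.26 ± 0.42 for Il12b (adjusted p = 0.000116), -1.73 for P2ry10 (adjusted p = 0.00712), -1.57 for Serpinb6b (adjusted p = 0.0102) and 2.33 for the hepatocyte gene Ahsg (adjusted p = 0.0412). In all 8 of 6307 genes passed (565 before adjustment), without overlap between groups, as passing all but requires (26.1% of all tested genes, chance share 20%). The count was 21, 14, 79, 13 and 17 without sham 1, sham 2, pIVCL 1, pIVCL 2 and pIVCL 3, and within batch 2021.3 it was 70, 6 of them shared. In the batch-term fit Ly6c2, P2ry10, Serpinb6b and Ahsg no longer passed, and Ly6c2 was at -0.88 with doublets kept and at -0.34 with finer clusters. The split was 1 higher and 3 lower with that term, 1 and 2 with doublets kept, 1 and 1 with stricter filters and 0 and 2 with finer clusters. F13a1 was not tested with doublets kept or finer clusters. The neutrophil list made up 0.000112% of the molecules of this class in sham and 0.0849% in pIVCL (0.246% in pIVCL 2). With finer clusters the Xcr1 cluster of this class went from 157 to 112 cells, and an unnamed cluster led by the progenitor gene Prtn3 from 48 to 94. The F13a1 and Ly6c2 rises therefore cannot be assigned to dendritic cells.

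The macrophage list was higher, and interferon gamma, NF-kB and mitochondrial lists lower, in dendritic cells at the preset correlation only (adjusted p = 0.245, 0.754, 0.510 and 0.716 with an estimated correlation). Of 14 macrophage-list genes 2, F13a1 and Ly6c2, rose, with 5 up over the list alone, a median of 0.13 and a mean of 0.92 (adjusted p = 2.74e-07, adjusted p = 0.245 with an estimated correlation, alternatives from 3.21e-09 to 0.8). Its call ended with doublets kept (median -0.02, adjusted p = 0.8) and with finer clusters (adjusted p = 0.795). Kupffer-cell transcripts made up 0.137% of the molecules of this class in sham and 0.254% in pIVCL (0.346% in pIVCL 2). Of 14 interferon gamma genes 0 passed over all genes and 1 fell over the list alone (median -0.76, adjusted p = 0.00667, adjusted p = 0.754 with an estimated correlation, alternatives from 4.03e-15 to 0.829). This call ended without sham 2, where the direction turned (adjusted p = 0.829), without pIVCL 2 (adjusted p = 0.0964), with batch as a term (adjusted p = 0.0816) and with doublets kept (adjusted p = 0.164). Of 15 NF-kB genes 0 passed either way (median -0.45, adjusted p = 0.0056, adjusted p = 0.510 with an estimated correlation, lowest alternative 3.99e-05). Here the call ended with batch as a term (adjusted p = 0.216), within batch 2021.3 (adjusted p = 0.165) and without sham 1 (adjusted p = 0.176). Of 13 mitochondrial genes 4 fell over the list alone (median -0.40, adjusted p = 3.58e-05, adjusted p = 0.716 with an estimated correlation, lowest alternative 1.2e-12). They did not pass with doublets kept (adjusted p = 0.0884) or stricter filters (adjusted p = 0.087). Of 20 hepatocyte genes Ahsg rose, with 8 up over the list alone (median 1.53, adjusted p = 1.37e-17, adjusted p = 0.536 with an estimated correlation, lowest alternative 9.22e-31).

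The TGF-beta list was higher, and unfolded protein and sinusoidal identity lists lower, in dendritic cells at the preset correlation only (adjusted p = 0.716, 0.754 and 0.754 with an estimated correlation). Of 8 TGF-beta targets (median 0.44, mean 1.42, adjusted p = 0.0471, adjusted p = 0.716 with an estimated correlation, lowest alternative 0.000126) the call ended without sham 2 (adjusted p = 0.168), pIVCL 1 (adjusted p = 0.195) or pIVCL 2 (adjusted p = 0.566), with batch as a term (adjusted p = 0.0816), with no filter on low counts (adjusted p = 0.0851) and with stricter filters (adjusted p = 0.0615). Of 12 unfolded protein genes (median -0.27, adjusted p = 0.0376, adjusted p = 0.754 with an estimated correlation, lowest alternative 6.21e-06) it ended without sham 2 (adjusted p = 0.168) and without pIVCL 1 (adjusted p = 0.552). Of 21 sinusoidal identity genes 2 fell over the list alone (median -0.15, adjusted p = 0.0356, adjusted p = 0.754 with an estimated correlation, alternatives from 1.36e-08 to 0.826). The call ended without sham 2, at a median of 0.24 (adjusted p = 0.659), without pIVCL 1 (adjusted p = 0.152), without pIVCL 3, where the test turned upward (adjusted p = 0.739), and with stricter filters (adjusted p = 0.826). It also ended with batch as a term (adjusted p = 0.195), with a replicate block, where it turned upward (adjusted p = 0.560), with doublets kept (adjusted p = 0.275) and with finer clusters (adjusted p = 0.286).

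The pIVCL effect on Pdgfb, Tiam1, Slco2a1 and Ajuba differed between endothelial and Kupffer cells, the classes compared by an interaction test. Pdgfb rose in endothelial cells and was at -0.12 in Kupffer cells, and Tiam1 and Slco2a1 fell in endothelial cells and were at -0.40 and -0.65 in Kupffer cells. As Kupffer minus endothelial log2 fold change, the differences were -2.76 for Pdgfb (adjusted p = 0.000208), -2.13 for Ajuba (adjusted p = 0.0243), 2.02 for Slco2a1 (adjusted p = 0.00404) and 3.57 for Tiam1 (adjusted p = 0.0248) by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. The chemokine gene Pf4, at 1.11 in Kupffer and -0.45 in endothelial cells, differed by 1.49 (adjusted p = 0.0248) and the tetraspanin gene Cd63 by 2.19 (adjusted p = 0.0167). Differences also passed for Gatm at 1.69 (adjusted p = 0.0336), Icam1 at -0.87 (adjusted p = 0.0498) and Lyz2 at -1.04 (adjusted p = 0.0248). Of 11958 genes 79 passed, 33 higher and 46 lower in Kupffer cells, from 1394 before adjustment. With DESeq2 size factors 58 were higher and 50 lower. Without sham 1, sham 2 or pIVCL 1 the count was 1, 7 and 229, and with batch as a term it was 5.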

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

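The test of hepatocyte transcripts in T cells, both tests of the fibrillar collagen list and the test without clusters 13, 17 and 23 were chosen after the result was seen.

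The effect of pIVCL differed between endothelial and Kupffer cells for 79 genes (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 9 of them are given here as Kupffer minus endothelial log2 fold change. Differences below 0 were those of Pdgfb (-2.76, adjusted p = 0.000208), Ajuba (-2.13, adjusted p = 0.0243), Lyz2 (-1.04, adjusted p = 0.0248) and Icam1 (-0.87, adjusted p = 0.0498). Those above 0 were Tiam1 (3.57, adjusted p = 0.0248), Cd63 (2.19, adjusted p = 0.0167), Slco2a1 (2.02, adjusted p = 0.00404), Gatm (1.69, adjusted p = 0.0336) and Pf4 (1.49, adjusted p = 0.0248).

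Among cells used in no comparison of genes, 2 unnamed clusters were singled out because every pIVCL library held a larger share than either sham library, so no p is given for that difference. Cluster 15, macrophages with Cx3cr1, Ms4a7 and Mmp13 that the Clec4f threshold kept out of the Kupffer class, held 2.43 ± 0.378% of pIVCL and 0.935 ± 0.00945% of sham cells. Cluster 36, with Prtn3, Myb and Cpa3, held 0.496 ± 0.136% against 0.0464 ± 0.0657%.

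Hepatocyte transcripts were higher as a list in stellate cells and fibroblasts after pIVCL at the preset correlation only. If free RNA of lysed hepatocytes had entered every cell alike, T cells should have gained as much. Their pIVCL to sham ratio was 1.08 (highest pair of libraries 2.00) against 3.76 in the stellate class (lowest pair 2.86), which argues against that as the whole cause. As sham T cells held 0.121 and 0.0553%, a smaller gain in them stays open. Ratios of 2.89 in dendritic, 2.17 in endothelial and 2.09 in NK cells and ILC1 leave a part from free RNA open. It was 1.13 in Kupffer cells, where the list's median log2 fold change was 1.61. If few joined cells carried them, the ratio should have collapsed without the 10% of cells richest in the list, and it was 3.45, which argues against that. A gain in stellate cells themselves remains possible and was not tested apart.

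Fibrillar collagen and activation genes were lower as a list in the whole stellate and fibroblast class at the preset correlation only (adjusted p = 0.360 with an estimated correlation), with no gene past the threshold. With fewer fibroblasts in the class after pIVCL the list should not be lower in stellate cells alone, and in cluster 8 its median was 0.64 against -0.67 in the whole class, a result that fits a change of mixture. A difference between the batches could not be told apart, since within batch 2021.3 the median was -0.50 (adjusted p = 0.117). Stellate activation after pIVCL was not tested apart from these, and in cluster 8 alone, where the list was higher (adjusted p = 0.000123), Kupffer-cell transcripts were higher too (median 0.93, adjusted p = 0.00874) and quiescent genes did not pass (median -0.0748, adjusted p = 0.677).

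Many endothelial genes changed between sham and pIVCL. A batch difference cannot be told apart, since the 838 genes of pIVCL 1 against the shams of its own batch rest on that library alone, and splits that set a sham apart keep pIVCL 1 in the other arm and so give no fair yardstick. With every library thinned to equal molecules 444 of all 610 calls (72.8%) were kept. All 598 of these genes tested there kept their direction, which their lack of overlap between groups nearly fixes. As thinning also lowers power, a part of depth in the calls lost cannot be told apart. Another mix of large-vessel and cycling cells is argued against by the fit without clusters 13, 17 and 23. There 570 of the 594 calls that could be tested (96.0%) were kept, and the rest of the 610 were not tested. An effect of the ligation on endothelial cells was not tested apart from these.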

How the results depend on the processing

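Alternatives marked here as cluster 8 alone, with cluster 11 and mixed clusters counted were chosen after the results were seen, as were the gene names outside the rule. Genes that passed had no overlap between the libraries of the groups, which nearly fixes their direction in fits to the same libraries. A kept direction below is therefore no separate support. Of 92 named genes called, all kept direction in every fit that left out 1 library, with batch as a term, within batch 2021.3, with a replicate block and by DESeq2, and 38, 29, 91, 43 and 60 kept their call without sham 1, sham 2, pIVCL 1, pIVCL 2 and pIVCL 3. With batch as a term 56 kept it, within batch 2021.3 73, by DESeq2 90 and with DESeq2 size factors all 92. Of 45 list calls 0 were kept with an estimated correlation, 26 with batch as a term, 32 within batch 2021.3, 45 with DESeq2 size factors and 38, 35, 37, 38 and 39 without the libraries in the order above. Without pIVCL 1 batch and group coincide, so the larger counts there cannot be assigned to either. Libraries of a group differed beyond sampling noise in every class (chi-square per gene from 2.06 for T cells of the shams upward), and low depth and cell number limit the smaller classes. Where a call or direction changed the cause was not tested, except that leaving libraries out lowers the number of samples.

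Counts of genes by setting follow. With no expression filter there were 1779 endothelial, 417 Kupffer, 382 stellate and fibroblast, 42 T, 54 NK and ILC1 and 108 dendritic-cell genes and 229 interaction genes. Under a batch term there were 335 endothelial, 0 Kupffer (edgeR, 907 before adjustment), 104 stellate and fibroblast, 2 T, 0 NK and ILC1 (edgeR, 219 before adjustment), 4 dendritic-cell and 5 interaction genes. Within batch 2021.3 there were 123 stellate and fibroblast, 5 NK and ILC1, 70 dendritic-cell and 304 interaction genes. DESeq2 Wald tests gave 1067, 120, 201, 2 and 16 genes in endothelial, Kupffer, stellate and fibroblast, NK and ILC1 and dendritic cells.

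With stricter filters edgeR gave 1 Kupffer, 32 stellate and fibroblast, 2 dendritic-cell, 0 T (458 before adjustment, DESeq2 4 at the usual filter) and 0 NK and ILC1 genes (157 before adjustment). Finer clusters gave 0 Kupffer (edgeR, 1244 before adjustment), 2 dendritic-cell and 17 interaction genes, doublets kept gave 3 dendritic-cell and 153 interaction genes, cluster 8 alone gave 15 stellate genes and cluster 11 added gave 0 Kupffer genes (edgeR, 1158 before adjustment).

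The replicate numbers are shared by name only, and no label pairs the libraries. Deviations from the group mean of same-numbered libraries correlated at -0.086 (endothelial, number 1) and 0.0838 (stellate and fibroblast, number 1). With 2 sham libraries, whose deviations mirror each other, these values cannot tell whether the numbers pair the libraries. With replicate number as a block there were 383 endothelial, 11 NK and ILC1, 89 dendritic-cell and 207 interaction genes and 2 T-cell lists. In these fits 71 of 92 named genes and 37 of 45 lists kept their call, and the sinusoidal identity list in dendritic cells turned to 0.0865.

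Leaving out 1 library moved the counts from 62 (sham 1) to 2566 (pIVCL 1) in endothelial and from 0 (sham 1, sham 2 and pIVCL 2) to 416 (pIVCL 1) in Kupffer cells. They moved from 7 (sham 2) to 310 (pIVCL 1) in stellate and fibroblast, from 1 (pIVCL 3) to 121 (pIVCL 1) in T and from 0 (sham 1, pIVCL 2 and pIVCL 3) to 77 (sham 2) in NK and ILC1. For the rest they moved from 13 (pIVCL 2) to 79 (pIVCL 1) in dendritic-cell and from 1 (sham 1) to 229 (pIVCL 1) in interaction genes. Lists passing numbered 4 without either sham and 1 without any pIVCL library in NK and ILC1, and in T cells 3 without sham 1 or pIVCL 3, 6 without sham 2 and 4 without pIVCL 1 or pIVCL 2. In dendritic cells medians ran from -0.74 (pIVCL 2) to 0.24 (sham 2) for sinusoidal identity, whose test turned without pIVCL 3 (0.11), and from -1.26 (sham 1) to 0.25 (sham 2) for interferon gamma genes. In Kupffer cells MHC class II genes ran from -0.55 (sham 1) to -0.19 (pIVCL 2), and their test turned without sham 2 (-0.21). In T cells the medians ran from -0.35 (pIVCL 1) to 0.49 (sham 2) for immediate-early and from -0.47 (sham 2) to 0.82 (sham 1) for hepatocyte genes. Share differences ran from -0.247 (pIVCL 2) to 0.205 (pIVCL 3) points for cholangiocytes, with -0.0684 without sham 2. They ran from -0.980 (sham 1) to 0.809 (sham 2) for T cells, with 0.422 without pIVCL 1 and 0.177 without pIVCL 2, and from -2.95 (pIVCL 1) to 5.97 (pIVCL 3) for endothelial cluster 6.

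The number of lists passing with an estimated correlation was 0 in endothelial, 0 in Kupffer, 0 in stellate and fibroblast, 0 in T, 0 in NK and ILC1 and 0 in dendritic cells. With the preset correlation and other settings, lists passing numbered 5 in dendritic and 4 in Kupffer cells with batch as a term and 6 in Kupffer cells with other-cell lists removed. At that correlation NK and ILC1 had 10 with no filter, 3 within batch 2021.3, 7 with doublets kept and 0 with stricter filters, and in T cells 2 with no filter and 2 within batch 2021.3.

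Results that reversed were these, as log2 fold changes or medians. Under a batch term and within batch 2021.3, in that order, Kupffer quiescent stellate genes stood at 0.57 and 0.62 (adjusted p = 0.0136 and 0.000476, against a median of 0.12, a mean of -0.02 and a test on the lower side without a batch term, adjusted p = 0.995) and NF-kB genes at 0.22 and 0.21. In stellate cells and fibroblasts 4 endothelial lists passed on the lower side in these 2 fits and did not pass over all libraries without a batch term. Of these, capillarization genes kept their direction (adjusted p = 3.25e-06 and 0.00307, against 0.291) and the others turned. Sinusoidal identity genes stood at -1.76 and -1.75 (adjusted p = 2.53e-18 and 1.31e-17, against -0.05, a mean of 0.13, a test on the higher side and adjusted p = 0.778 without a batch term). Endothelial transcripts stood at -2.27 and -2.26 (adjusted p = 1.29e-16 and 2.97e-16, against 0.14 and adjusted p = 0.769) and periportal genes at -0.80 and -1.37 (adjusted p = 0.0283 and 0.0182, against 0.47 and adjusted p = 0.159). In cluster 8 alone fibrillar collagen genes stood at 0.64, quiescent genes at -0.0748, Kupffer transcripts at 0.93 and Pid1 at 0.85. In dendritic cells the macrophage list stood at -0.0151 and Ly6c2 at -0.88 with doublets kept, and Ly6c2 at -0.34 with finer clusters. Share differences reversed for cholangiocytes (-0.0294 points with doublets kept), plasmacytoid dendritic cells (0.0261 with stricter filters) and T cells (0.506 with stricter filters, 0.359 as a share of named classes and 0.133 with mixed clusters counted).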

Other observations

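No test in this part was chosen to explain a result; the gene lists were fixed before the data were examined.

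Several stress and signalling lists did not pass in the classes where the model might be thought to act. In endothelial cells Notch genes (11, median 0.03, camera adjusted p = 0.542) held 1 rise, the tip-cell ligand gene Dll4 (0.93), and 1 fall, Dll1 (-1.13). Oxidative stress targets of NRF2 (13, median 0.04, mean -0.08, adjusted p = 0.681) held 1 fall, Nqo1 (-1.17). Fibrillar collagen genes (15, median 1.08, adjusted p = 0.0799), MHC class II genes (6, median 0.69, adjusted p = 0.0588) and proliferation genes (22, median 0.31, adjusted p = 0.107) did not pass there. Of the fibrillar genes Col5a1 (2.24) and Col6a3 (1.96) rose and Thbs2 (-1.79) fell, and that list passed with batch as a term (adjusted p = 0.01) and within batch 2021.3 (adjusted p = 0.00782), but not with an estimated correlation (adjusted p = 0.617). Nor did heme and iron handling genes (19, median 0.12, adjusted p = 0.438), unfolded protein response genes (15, median 0.18, adjusted p = 0.228) and immediate-early genes (20, median -0.36, adjusted p = 0.273). At the preset correlation the lowest alternatives were 0.0016 for MHC class II, 0.0217 for proliferation and 0.000341 for immediate-early genes. In Kupffer cells NRF2 targets (13, median 0.01, mean -0.02, adjusted p = 0.956), unfolded protein response genes (13, median 0.15, adjusted p = 0.931) and adhesion genes (20, of which Vcam1 rose, median -0.19, adjusted p = 0.106, lowest alternative 0.000501) did not pass. In stellate cells and fibroblasts the same held for Notch genes (11, median 0.27, adjusted p = 0.0537, lowest alternative 0.014), NRF2 targets (13, median -0.14, adjusted p = 0.566) and TGF-beta targets (14, median -0.37, adjusted p = 0.316).

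Classes too small for gene tests still gave cell numbers. In the order sham 1, sham 2, pIVCL 1, pIVCL 2, pIVCL 3 there were 17, 16, 56, 84 and 488 B cells, 30, 18, 23, 38 and 60 monocytes, 57, 49, 19, 45 and 23 plasmacytoid dendritic cells, 43, 31, 20, 49 and 15 cholangiocytes. There were 44, 4, 26, 21 and 417 hepatocytes, and 5, 0, 4, 22 and 27 neutrophils. Plasmacytoid dendritic cells were 1.32% of sham and 0.974% of pIVCL cells (exact permutation p = 0.4, a difference of -0.347 points that became -0.526 without pIVCL 2 and -0.671 with mixed clusters counted), cholangiocytes 0.916% and 0.930% (exact permutation p = 1), and unnamed clusters 9.65% and 11.1%.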
